A study of Mus musculus with 22 samples.

How the data were processed

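RNA from tagged ribosomes and from the unbound supernatant of CA1 dissections was amplified with the Nugen Ovation RNA-Seq System V2, treated with a single-strand nuclease, made into libraries with the Illumina TruSeq DNA kit v2 and size-selected on a gel, per the labels' protocols. Amplified RNA from small dissections without molecular identifiers does not count molecules. The submitters' processing notes name CASAVA 1.9, STAR 2.1.1d, Cufflinks 2.0.2 and the mouse build mm9; their order and settings are not given in the sources used here. The authors deposited FPKM values, fragments per kilobase and per M fragments mapped, in a paired-end table and a single-end table, each with a column per library and per part of the transcript, per the file headers. The part used here joins the 5′ UTR, the coding sequence and the start of the 3′ UTR; in the deposited annotation 86.8% of transcripts with both parts keep 201 bases of the 3′ UTR in it. The rest of the 3′ UTR forms the other part. FPKM of both parts cover 29848 genes, and no scaling between libraries by the authors is given in the sources used here. The authors' annotation is in mm9 and all coordinates are from it, 1-based, for the longest model of a symbol. Gene symbols are those of the files, so that Map2 appears as Mtap2 and Zbtb18 as Zfp238. Strand use in the counting is not given in the sources used here, so overlapping genes cannot be separated.

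FPKM keep no counts, so no interval for counting error was computed. Depth was estimated from the deposited FPKM: for genes with one transcript of at least 1500 bases, the value of 1 read was taken from the spacing of low values, and 89.1 to 96.4% of them lay within 0.15 reads of 1, 2 or 3 reads. The rule that picks this spacing was set after the values were seen. In the paired-end runs the unit counted as 1 read is 1 fragment, a pair of reads. The paired-end runs came to 5.68 to 35.3 M mapped fragments and the single-end runs to 0.514 to 10.6 M mapped reads. A gene with a low value in a shallow library therefore rests on few reads. Of the values of tested genes in the 8 immunoprecipitates, 28.3% were 0.

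The comparisons, the tests, the expression minimum, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined; the coding part as the measure was chosen after the headers were read. Groups came from the labels for behaviour, location and fraction. The paired-end table was the main one, because fragments are placed by both ends, and the single-end run of each library was a technical repeat that never entered n. Tests were made within a table only. Each library was divided by its median ratio to the geometric mean over libraries, over 672 genes above 0 in all 8 immunoprecipitates or 643 genes above 0 in all 11 libraries. Genes with a mean scaled FPKM of at least 1 were tested on log2(scaled FPKM + 1), so fold changes are on that scale and understate the change of low genes. Scaled FPKM in the immunoprecipitate comparisons and in those with supernatants come from these separate scalings and differ slightly.

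limma 3.58.1 in R 4.3.3 fitted group means with trended empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The 8 immunoprecipitates were fitted in 4 groups with 1 shared spread (4 residual degrees of freedom), and the 11 libraries by location and fraction with behaviour as covariate (6 residual degrees of freedom). The dendrite and soma contrast averages both behaviours. All tests were two-sided. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison with at least 5 tested members, then with an estimated correlation, and with fry, which asks whether the members of a list move one way and does not compare them with other genes. There were 27 lists with 576 symbols, of which 7 have no row in the tables. For the 6 genes always named in the dendrite and soma comparison an exact permutation test was also run.

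Named genes followed a rule. The first part takes, per comparison and direction, the 10 genes with the largest change past the threshold, with a mean of at least 10 in the higher group, no overlap between libraries of the groups and the same direction in the single-end table. With fewer than 5 such genes it takes the 5 largest with an unadjusted p under 0.05 under the same other conditions, given as values that did not pass. The second part takes the 4 members with the highest mean of each list described. The third part always names Camk2a, Map2, Arc, Shank1, Dlg4 and Ddn for dendrite and soma; Arc, Fos, Npas4, Egr1, Junb, Nr4a1, Homer1 and Bdnf for fear conditioning; and Camk2a, Gfap, Mbp, Gad1 and C1qa for the supernatants. Members named because they passed adjusted over the list alone, and other genes said to be named after their values were seen, are outside it.

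Alternatives were pseudocounts of 0.1 and 5, no expression minimum and one of 5, FPKM as deposited, quantile normalization, the single-end table, the mean of both tables, robust moderation, a replicate block, the rest of the 3′ UTR, and leaving out each library. The scripts were tested on simulated data with the libraries' own spread and with 0.1 of it, with 200 genes changed by known folds in each of 5 runs; at the smaller spread 98.8% of genes changed by 1 on the log2 scale were recovered between dendrite and soma. The changed genes were drawn from the better expressed ones, and residuals were shuffled gene by gene. All recovery rates given below therefore do not cover low genes, disturbances of whole libraries or correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.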

Results

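Ribosome-bound mRNA was measured in the CA1 field of the mouse hippocampus. The double transgenic animals carry a Camk2a-driven transactivator that switches on ribosomal protein L10a fused to GFP, so that an antibody to GFP pulls down ribosomes of excitatory neurons. Tissue was dissected into dendrites and cell bodies (soma) from mice kept in the home cage or fear conditioned, a training that pairs a place or cue with a shock. The 22 samples were 11 libraries, each with a paired-end and a single-end run. There were 8 immunoprecipitates, 2 for each behaviour and location, and 3 supernatants, which hold the RNA left unbound (home cage dendrite 2, fear conditioned dendrite 2 and fear conditioned soma 2). Both runs of a library counted as 1 replicate. The labels do not say that libraries came from separate animals, so p-values may measure only the spread between these samples.

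The FPKM of low genes put the paired-end runs at 5.68 to 35.3 M mapped fragments and the single-end runs at 0.514 to 10.6 M mapped reads. Paired-end immunoprecipitates listed 3220 to 12205 genes above 0, and the supernatants 10344 to 13164. Rpsa, which encodes a protein of the small ribosomal subunit, took 74.0% of the summed FPKM of the home cage soma immunoprecipitate 2, and Mir135b took 26.9% in the fear conditioned dendrite immunoprecipitate 1. Hprt, a housekeeping gene, had an FPKM of 0 in 3 immunoprecipitates, so a value of 0 is given below as listed at 0. Across genes, which are not independent replicates, Pearson's r of log2 FPKM was 0.200 to 0.418 between replicate immunoprecipitates of one group and 0.171 to 0.412 between other immunoprecipitates. It was 0.567 to 0.727 between supernatants. Between the 2 runs of one library it was 0.348 to 0.627 for immunoprecipitates, with a median of 0.584. Agreement in direction with the single-end table is therefore a weak check. The fear conditioned dendrite immunoprecipitate 1 had an r of 0.70 with the home cage dendrite supernatant in the paired-end table and of 0.36 in the single-end table.

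**Figure D1:**
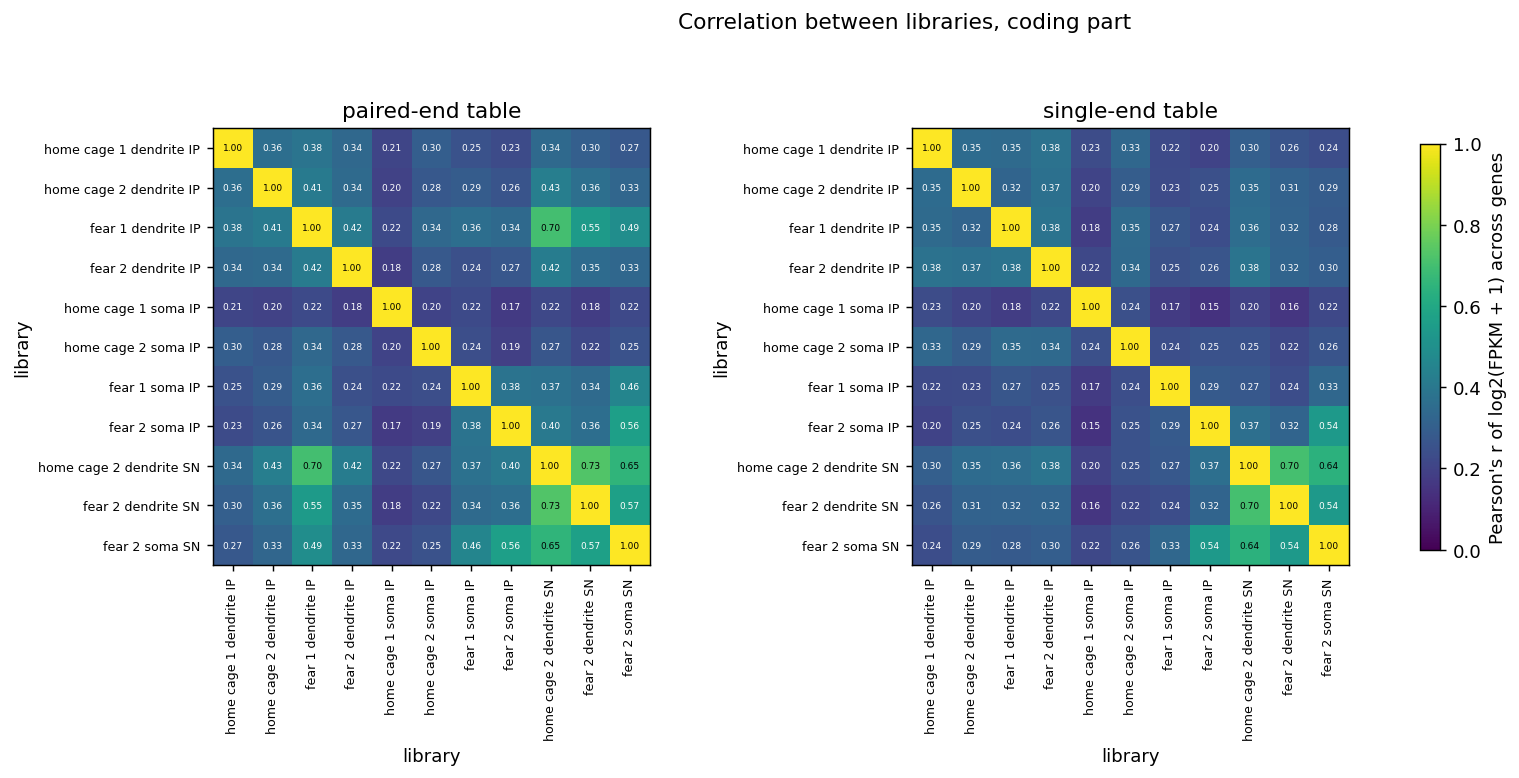
Heat maps of Pearson's r between the 11 libraries, computed across genes on log2(FPKM + 1) of the coding part, in the paired-end table (left) and the single-end table (right); each cell prints its r and SN stands for supernatant. In the paired-end table the fear conditioned dendrite immunoprecipitate 1 and the home cage dendrite supernatant reach 0.70.

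The first comparison asked which ribosome-bound mRNAs differ between dendrites and cell bodies. Camk2a, which encodes the alpha subunit of a calcium-dependent kinase and is a classic dendritic mRNA (chromosome 18, 61085286 to 61147806), had a scaled FPKM of 268 ± 207 (SD, n = 4) in dendrite and 30.0 ± 16.4 (SD, n = 4) in soma immunoprecipitates, a log2 difference of 2.86 (SE 1.10). Dlg4, a scaffold of the postsynaptic density (chromosome 11, 69832107 to 69859033), had 27.8 ± 19.4 against 1.60 ± 1.38, a log2 difference of 3.22 (SE 1.10). Ddn, which encodes dendrin (chromosome 15, 98634213 to 98638356), had 16.2 ± 15.2 against 1.28 ± 0.637, a log2 difference of 2.48 (SE 1.05). In the scaled paired-end table each of these 3 genes was higher in every dendrite library than in any soma library, with a two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.0571 adjusted over the 6 genes always named. Other settings broke this separation: in the single-end run, as deposited, the fear conditioned dendrite library 1 had Ddn at 0 and Dlg4 at 2.64 against up to 2.86 and 12.6 in soma, and in the paired-end run as deposited Camk2a was 63.6 in home cage dendrite 1 and 109 in fear conditioned soma 2. Over all 2935 genes tested their limma adjusted p was 0.657, so none of them passed. The unbound RNA differed the same way in the paired-end run as deposited. Camk2a was at 113 and 184 in the home cage and fear conditioned dendrite supernatants and at 41.3 in the only soma supernatant. Dlg4 was at 14.3 and 14.8 against 3.18, and Ddn at 15.4 and 8.53 against 4.69. The difference was therefore not confined to ribosome-bound RNA.

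The other 3 genes always named overlapped between dendrite and soma. Mtap2, a dendritic microtubule protein, had 23.6 ± 25.7 against 10.6 ± 7.15 (SD, n = 4; log2 difference 0.70, exact p = 0.571). Shank1, another postsynaptic scaffold, had 36.9 ± 23.9 against 38.8 ± 61.1, while its log2 difference was 1.01 (exact p = 0.429). Arc, an activity-induced synaptic gene, was listed at 0 in home cage dendrite 1 and at 0.618 in 2, and at 0.428 and 26.8 in fear conditioned dendrite 1 and 2. In soma Arc was listed at 0 in both home cage libraries and at 2.18 and 0.850 in the fear conditioned ones (exact p = 0.714).

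Among genes with unadjusted p under 0.05 that met the other naming conditions, the largest positive differences were those of Atpase6, Glul, Ndrg2, mt-Nd4 and Celf4. Atpase6 had 1690 ± 193 in dendrite and 153 ± 159 in soma (SD, n = 4), a log2 difference of 4.30 (SE 0.81) and the smallest adjusted p, 0.415. The annotation lists it on chromosome 1 from 24620810 to 24621651 and on 1 more chromosome under the name of a mitochondrial gene, so shared reads make its value uncertain. Glul, the astrocytic glutamine synthetase (chromosome 1, 155747075 to 155756844), had 45.3 ± 14.7 against 2.13 ± 0.912 (log2 3.88). Ndrg2 had 29.2 ± 23.5 against 0.875 ± 0.815 (log2 3.77), and Celf4, an RNA-binding protein, had 64.4 ± 32.3 against 10.5 ± 14.4 (log2 3.29). The mitochondrial mt-Nd4 (chromosome M, 9876 to 11542) was listed at 14.7, 28.0, 41.1 and 37.6 in the dendrite libraries. In the soma libraries it was listed at 0, 0, 14.2 and 1.08. Whether the RNA counted for mt-Nd4 and Atpase6 was bound to the tagged ribosomes was not tested, so neither is shown to be a ribosome-bound dendritic mRNA. The largest negative differences were those of Pfn1, Ddx26b, Mical2, Miat and mKIAA4050. Pfn1, which encodes the actin-binding profilin, was listed at 0, 0.619, 5.15 and 3.86 in dendrite and at 18.3, 6.00, 97.2 and 52.8 in soma. Ddx26b was listed at 0, 0, 0.281 and 0 in dendrite and at 55.0, 0.570, 19.6 and 1.62 in soma, and Mical2, an actin-oxidizing enzyme, at 0, 0.203, 0.446 and 0.302 against 6.24, 30.0, 5.57 and 4.50. mKIAA4050 was listed at 0, 0, 3.67e-65 and 0.0279 against 0.537, 85.3, 2.84 and 2.75. Miat, a long noncoding RNA (chromosome 5, 112642248 to 112657968), had 0.0354 ± 0.0375 against 10.3 ± 9.95 (log2 -2.94). None of these 10 genes passed the test.

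By limma 0 genes passed, with 130 at an unadjusted p under 0.05, 53 of them higher and 77 lower in dendrite; the same model with robust moderation also gave 0. In simulated data with this spread the test recovered 0.8% of the better expressed genes changed by 1 on the log2 scale, 2.4% at 2, 30.4% at 4 and 78% at 6. The median log2 difference of all genes was -0.33 after scaling and 0.12 with FPKM as deposited, and list medians stand against that shift.

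**Figure D2:**
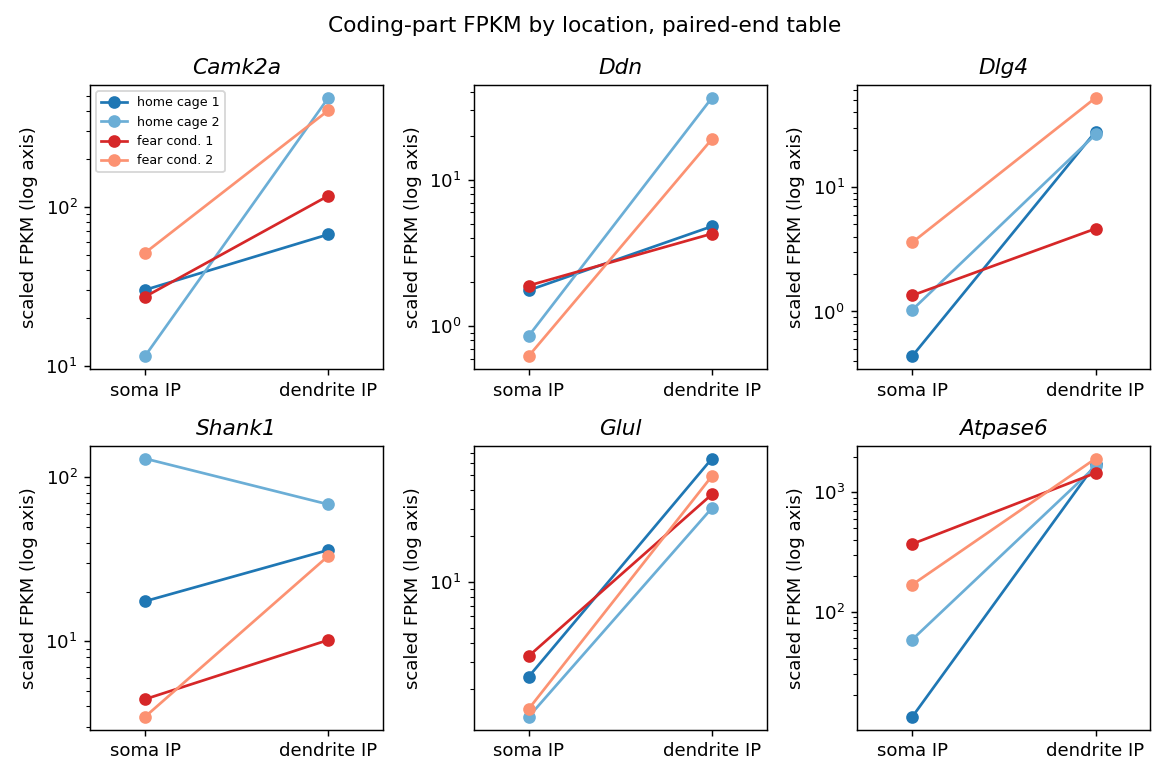
Scaled FPKM (log axis) of genes named in the text in the 8 paired-end immunoprecipitates (IP); points are libraries and lines join those of the same behaviour and number. Camk2a, Dlg4 and Ddn are higher in all 4 dendrite libraries than in all 4 soma libraries.

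Of the gene lists, 6 of 19 with at least 5 tested members passed by camera at its preset correlation, and 0 passed with an estimated correlation. Astrocyte markers rose in dendrite as a set, with all 10 tested members positive and a median log2 difference of 1.85 (adjusted p = 1.3e-07; adjusted p = 0.188 with an estimated correlation). No member passed over all genes, and 2 passed adjusted over the list alone, Glul and the lipoprotein gene Apoe (log2 3.17). Slc1a2, the main glial glutamate transporter, had 44.8 ± 43.0 against 3.95 ± 2.89 (SD, n = 4). The fear conditioned dendrite immunoprecipitate 1, which correlated with a supernatant, had Slc1a2 at 106, and the other 3 dendrite libraries had 32.7, 34.0 and 6.02. Without the home cage soma immunoprecipitate 2 the median of the astrocyte markers was 1.08 and they still passed.

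Cytoplasmic ribosomal proteins rose in dendrite as a set, with 51 of 78 members positive and a median of 0.60 (adjusted p = 4.7e-05; adjusted p = 0.458 with an estimated correlation). Rpl41 had 491 ± 653 in dendrite and 441 ± 639 in soma (SD, n = 4), and Rpl10 had 331 ± 585 against 91.4 ± 145. Rpsa ran the other way, with 107366 in the home cage soma immunoprecipitate 2 and 162 to 2028 in the other 7 immunoprecipitates. Translation elongation factors rose too, with 10 of 13 positive and a median of 1.06 (adjusted p = 0.00262; adjusted p = 0.331 with an estimated correlation). The list of that name was fixed with genes other than elongation factors in it, namely Tpt1, Eif3e, Eif3f, Eif3h, Gnb2l1, Naca, Btf3 and Fau. Its result is therefore that of a mixed list. Eef1a1 had 556 ± 335 against 273 ± 262 and Eef2 had 408 ± 588 against 229.7 ± 243, while Gnb2l1 had a log2 difference of -0.59. Textbook dendritic mRNAs rose with 19 of 33 positive and a median of 0.40 (adjusted p = 0.0446; adjusted p = 0.458 with an estimated correlation). Besides Camk2a, this list holds Eef1a1, Eef2 and Ppp1r9b, a spine protein with a log2 difference of 3.17 (SE 1.24). Without the home cage soma immunoprecipitate 1, the medians of translation elongation factors and cytoplasmic ribosomal proteins were 0.54 and 0.03 and neither passed; the ribosomal median was 1.19 without home cage soma 2 and 0.40 without fear conditioned dendrite 2, and passed. The call on textbook dendritic mRNAs was lost in 5 of the 8 fits that left out 1 immunoprecipitate: without home cage dendrite 1 (median 0.37) or 2 (0.09), home cage soma 2 (-0.14), fear conditioned soma 1 (0.38) or fear conditioned dendrite 2 (-0.09). It passed without fear conditioned dendrite 1 (0.92) and soma 2 (0.65). Of 11 other settings the textbook dendritic call held in 6. It was lost in the single-end table, with a pseudocount of 0.1, with an expression minimum of 5, with the replicate block and in the rest of the 3′ UTR.

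Glutamate receptors fell in dendrite as a set, with all 9 tested members negative and a median of -1.76 (adjusted p = 0.000213; adjusted p = 0.331 with an estimated correlation). Gria2, a subunit of AMPA receptors, had 2.57 ± 3.12 in dendrite and 22.2 ± 22.7 in soma (SD, n = 4). Grin1, the obligate subunit of NMDA receptors, had 4.59 ± 6.79 against 13.5 ± 13.2, and Gria1 had 2.15 ± 1.86 against 7.88 ± 5.83. With no expression minimum the 21 members of ionotropic and metabotropic glutamate receptors had a median of -0.02 and did not pass (adjusted p = 0.104). Voltage-gated ion channels fell with 11 of 13 negative and a median of -1.17 (adjusted p = 0.0460; adjusted p = 0.342 with an estimated correlation). The sodium channel gene Scn8a had 0.236 ± 0.416 against 19.4 ± 35.4, and Scn2a1 had a log2 difference of -0.45 (SE 0.98). The call on voltage-gated ion channels was lost in the single-end table and in 6 of the 8 fits that left out 1 immunoprecipitate: without home cage dendrite 1 (median -0.99) or soma 1 (-1.02), fear conditioned dendrite 1 (-1.09) or 2 (-1.11), or fear conditioned soma 1 (-1.35) or 2 (-1.21). No member of these 5 neuronal and translation lists passed, over all genes or adjusted over the list alone.

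The other lists did not pass. Postsynaptic density scaffolds had a median of 0.78 (adjusted p = 0.104), nuclear-encoded oxidative phosphorylation 0.46 (adjusted p = 0.155), microglia markers 0.61 (adjusted p = 0.226) and CA1 pyramidal neuron markers -1.08 (adjusted p = 0.292). Presynaptic genes had a median of -0.87 (adjusted p = 0.168), immediate early genes -1.38 (adjusted p = 0.240), and RNA-binding proteins 0.18 (adjusted p = 0.292). Neuronal transcription factors had -0.79 (adjusted p = 0.608), with Zfp238 at a log2 difference of -3.06 (SE 1.21) and Nfix at 3.02 (SE 1.11). Motor proteins had -0.61 (adjusted p = 0.725) and endoplasmic reticulum folding genes 0.24 (adjusted p = 0.377). Heat shock genes (-0.22), GTPase regulators (-0.36) and proteasome subunits (-0.25) had negative medians while camera placed them above the other genes (adjusted p = 0.432, 0.842 and 0.909). Marker lists with under 5 tested members had no set test. Their medians were 1.02 for 4 interneuron markers, 0.11 for 4 oligodendrocyte markers, 1.10 for 3 blood cell genes, -0.38 for 1 oligodendrocyte precursor gene, -0.80 for 1 vascular gene and 0.40 for 1 choroid plexus gene. The CA3 and CA2 marker Pcp4 was listed at 8.13, 29.0, 5.72 and 0.0878 in dendrite and at 0 in all 4 soma libraries, and passed adjusted over its list of 1 gene alone, not over all genes, and its difference had the other sign in the single-end table (-0.20). No dentate granule cell marker reached the expression minimum.

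**Figure D3:**
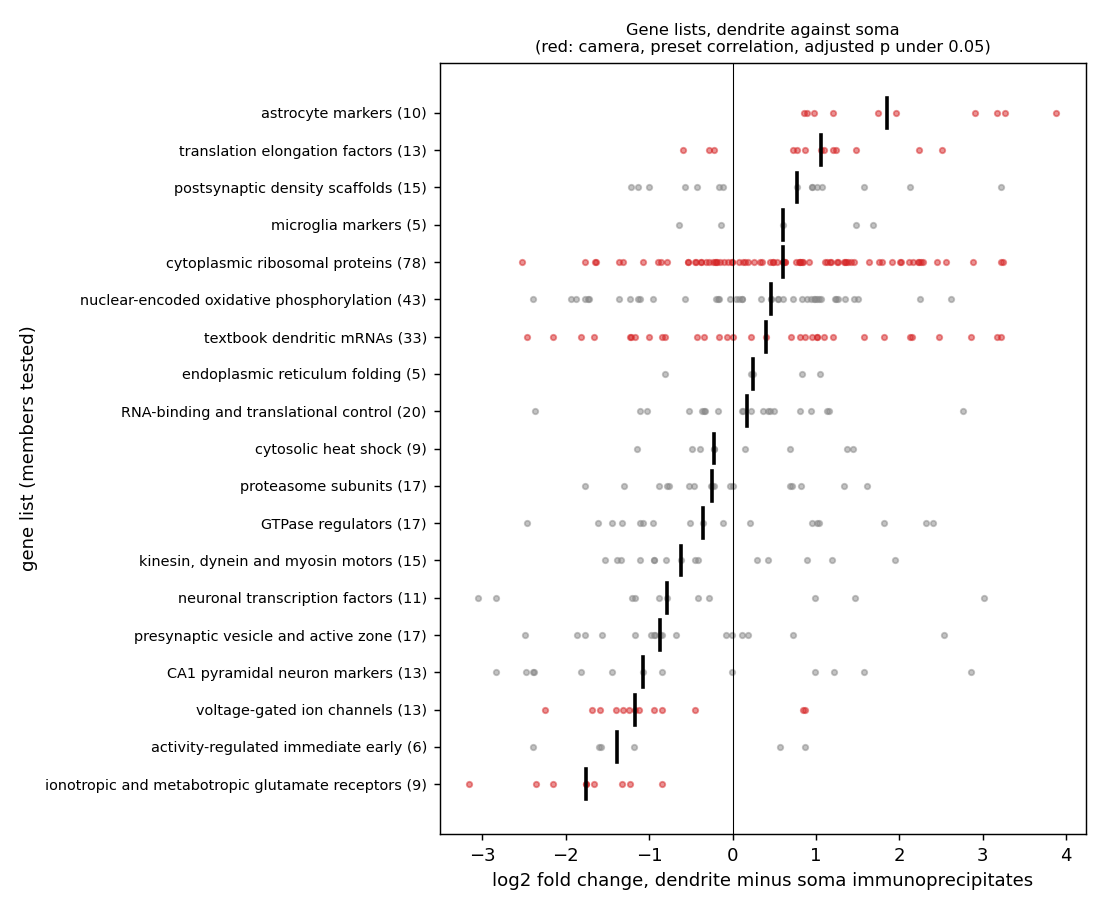
Log2 difference, dendrite minus soma immunoprecipitates, of each tested member (points) and the median (black bar) of each gene list with at least 5 tested members, whose number is in parentheses; red marks lists past an adjusted p of 0.05 by camera with the preset correlation. All 10 astrocyte markers lie above 0 and all 9 glutamate receptor genes lie below it.

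The next comparison asked which dendritic ribosome-bound mRNAs differ after fear conditioning, with 2 libraries against 2. By limma 0 genes passed, with 93 at an unadjusted p under 0.05, 59 higher and 34 lower, and robust moderation also gave 0. The exact p of 2 against 2 cannot go below 0.333. Vsnl1, a neuronal calcium sensor (chromosome 12, 11332051 to 11443455), had 51.8 ± 32.0 (SD, n = 2) after fear conditioning and 0.1201 ± 0.111 (SD, n = 2) in the home cage, a log2 difference of 5.42 (SE 1.77). Snap25, a synaptic vesicle fusion protein, had 476 ± 613 against 4.37 ± 2.38 (log2 5.28, SE 1.82). Zbp1 was listed at 24.0 and 129.5 after fear conditioning and at 0 and 0.756 in the home cage. Ndufa4, a respiratory chain protein, was listed at 4.53 and 1129, and the mitochondrial row AK163440 at 151 and 54.8, both against 0 in both home cage libraries. In the other direction, Msl1 had 2.06 ± 0.419 against 181 ± 56.2 (log2 -5.87, SE 1.82), Sept7 0.876 ± 0.625 against 59.7 ± 65.0 (log2 -4.44) and DQ716436 0.537 ± 0.598 against 113 ± 149 (log2 -4.91). C1ql3, a secreted synaptic protein, was listed at 0.0752 and 0 after fear conditioning and at 16.7 and 25.1 in the home cage, and Fam198a at 0.435 and 0 against 3.38 and 900.1. Each of these 10 genes had an adjusted p of 0.966.

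Of the immediate early genes, Btg2, an antiproliferative gene, was listed at 2.55 and 4.69 in the dendrite libraries after fear conditioning and at 105 and 0.254 in the home cage. Arc had the values given above, with a log2 difference of 2.31 (SE 1.36) and a limma adjusted p of 0.966. Fos, Npas4 and Nr4a1 were listed at 0 in both home cage dendrite libraries; after fear conditioning Fos and Npas4 were again at 0 and Nr4a1 at 0.139 and 0.0292. Egr1 was listed at 0.143 and 0 after fear conditioning, Homer1 at 0.636 and 0, Junb at 0.159 and 0.656 and Bdnf at 0.0911 and 0, each against 0 in both home cage libraries. The 6 immediate early genes tested had a median of 0.23 (adjusted p = 0.989).

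No list passed in dendrite. Presynaptic genes had 15 of 17 members positive and a median of 0.70 (adjusted p = 0.0945), and heat shock genes had 7 of 9 negative and a median of -1.46 (adjusted p = 0.0945). The chaperone gene Hsp90ab1 had 62.4 ± 35.9 after fear conditioning and 240.2 ± 172 in the home cage (SD, n = 2). Nuclear-encoded oxidative phosphorylation had 27 of 43 positive and a median of 0.55 (adjusted p = 0.137). Cytoplasmic ribosomal proteins had a median of 0.35 (adjusted p = 0.711) and astrocyte markers of -0.28 (adjusted p = 0.989). Of the astrocyte markers, the metallothionein gene Mt2 passed adjusted over the list alone and not over all genes; it was listed at 15.1 and 29.8 against 0 in both home cage libraries. Marker lists with under 5 tested members had no set test: oligodendrocyte markers had 4 of 4 positive and a median of 1.51, interneuron markers 3 of 4 and 1.60, and Ttr, the only choroid plexus gene tested, was listed at 0 and 121 against 0 and 0. The fear conditioned dendrite immunoprecipitate 1 of this comparison is the library that correlated with a supernatant. In simulated data with the spread of this comparison the test recovered 4.8% of genes changed by 4 on the log2 scale and 27.2% at 6.

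In soma, the same question gave a set of presynaptic genes that rose and a set of ribosomal protein genes that fell. Presynaptic vesicle and active zone genes had 16 of 17 members positive and a median of 2.03 (adjusted p = 4.77e-05; adjusted p = 0.531 with an estimated correlation). Vamp2, a vesicle fusion protein, had 42.6 ± 4.31 (SD, n = 2) after fear conditioning and 0.989 ± 0.955 (SD, n = 2) in the home cage, and Snap25 had 105 ± 60.3 against 11.6 ± 12.6. Syt1, the vesicle calcium sensor, was listed at 24.8 and 31.2 against 0 and 2.08. Cytoplasmic ribosomal proteins had 62 of 78 members negative and a median of -1.35 (adjusted p = 2.34e-07; adjusted p = 0.724 with an estimated correlation). Rpl41 had 88.4 ± 70.2 against 793 ± 850, Rps25 had 9.29 ± 4.78 against 418 ± 584, and Rpsa was listed at 680.0 and 162 against 2028 and 107366. No member of either list passed, over all genes or adjusted over the list alone. Detection parted by behaviour in these libraries. The paired-end home cage soma immunoprecipitates listed 5006 and 3220 genes above 0 at 13.6 and 14.1 M mapped fragments. The fear conditioned ones listed 9267 and 9211 at 19.1 and 29.9 M.

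The call on ribosomal proteins rested on the home cage soma immunoprecipitate 2, the library in which Rpsa took 74.0% of the FPKM and whose scaling factor was 0.199. Without it cytoplasmic ribosomal proteins had a median of -0.10 (adjusted p = 0.806) and presynaptic vesicle and active zone genes of 1.64 (adjusted p = 0.0823). Without home cage soma 1 the ribosomal median was -2.19, and with FPKM as deposited it was 0.28 beside 1.21 for all genes. Without the fear conditioned soma immunoprecipitate 2, the median of presynaptic vesicle and active zone genes was 1.12 and they did not pass.

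Single genes did not pass in soma either. By limma 0 of 2935 passed, with 179 at an unadjusted p under 0.05, 119 higher and 60 lower, and robust moderation also gave 0. Rtn-1A (chromosome 12, 73312739 to 73336726) had 110.2 ± 29.5 (SD, n = 2) after fear conditioning against 0.557 ± 0.788 (log2 6.23, SE 1.51). Gnai1, an inhibitory G protein subunit, had 141 ± 103 against 0.660 ± 0.489 (log2 6.22), and Atp1b1, a sodium pump subunit, had 129.96 ± 45.3 against 2.64 ± 2.42 (log2 5.31). AK192194 was listed at 253 and 4.49 against 0 and 0. Lower after fear conditioning were Zc3h18, with 1.01 ± 0.711 against 89.5 ± 34.7 (log2 -5.48), Rps14, with 1.11 ± 0.475 against 126 ± 128 (log2 -5.42), and Dcaf7, with 0.848 ± 0.742 against 72.7 ± 40.2 (log2 -5.26). 2610002J02Rik was listed at 0 in both fear conditioned libraries and at 15.9 and 153 in the home cage. All of these genes had an adjusted p of 0.605. In simulated data with this spread the test recovered 6% of genes changed by 4 on the log2 scale and 24.8% at 6. There, ribosomal proteins, shifted as a list, were found by camera in 4 of 5 runs, and other lists were called 2 times over these runs. The simulated genes were not correlated, so this does not show how camera fares where genes move together.

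Several immediate early genes, induced by neuronal activity, were higher in both fear conditioned soma libraries than in either home cage one, and all of these but Arc lay under the expression minimum. Npas4 was listed at 0.885 and 1.498 against 0.0530 and 0, and Egr1 at 1.77 and 2.80 against 0 and 0.171. Homer1 was listed at 2.71 and 1.38 against 0.502 and 0.481, Fos at 0.0267 and 0.249 against 0 and 0, and Arc at 2.18 and 0.850 against 0 and 0. These values lie near the floor, and the fear conditioned soma libraries listed more genes above 0. In the single-end run the scaled FPKM of Npas4 was 4.56 and 3.16 against 0 and 0, and that of Arc 8.03 and 1.42 against 0.643 and 0. Egr1 overlapped there, with 1.43 and 3.59 against 0.592 and 3.71, Homer1 had 0.241 and 1.57 against 0 and 0, and Fos was at 0 in all 4 libraries. In the paired-end run Nr4a1 was listed at 1.24 and 0.831 against 15.9 and 0.334, Junb at 0 and 0.1203 against 0.112 and 0, and Bdnf at 0 in all 4. In the single-end run Nr4a1 was lower in both fear conditioned soma libraries than in either home cage one, with 2.33 and 0.757 against 36.6 and 3.61. Junb there had 0 and 2.95 against 0 and 0. Arc (adjusted p = 0.738) and Nr4a1 (adjusted p = 0.722) were tested by limma and did not pass. A separation of 2 against 2 has an exact p of 0.333. The 6 immediate early genes tested had a median of -1.12 (adjusted p = 0.453). CA1 pyramidal neuron markers had a median of 0.86 (adjusted p = 0.375), with Neurod6 listed at 7.21 and 48.6 against 0.513 and 6.90 and a log2 difference of the other sign in the single-end table (-0.59).

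The interaction asked whether the difference after fear conditioning differs between dendrite and soma. Cytoplasmic ribosomal proteins were higher in this contrast, which is the dendrite difference minus the soma difference, with 60 of 78 members positive and a median of 1.81 (adjusted p = 2.71e-06; adjusted p = 0.721 with an estimated correlation). Rpsa had a log2 interaction of 6.08 (SE 2.06), Rps14 of 6.94 (SE 2.08) and Rpl41 of 0.92 (SE 2.04). Without the home cage soma immunoprecipitate 2 cytoplasmic ribosomal proteins had a median of 1.02 (adjusted p = 0.588). Cytosolic heat shock genes were lower in this contrast, with 8 of 9 negative and a median of -2.39 (adjusted p = 0.0444; adjusted p = 0.721 with an estimated correlation). Hsp90aa1 had -4.39 (SE 2.02), Hsp90ab1 -2.39 (SE 2.06) and Hspa8 -0.33 (SE 2.14). The call on cytosolic heat shock genes was lost in 7 of the 8 fits that left out 1 library: without home cage dendrite 1 (median -2.24) or 2 (-1.22), home cage soma 1 (-1.78) or 2 (-2.75), fear conditioned dendrite 1 (-1.90), or fear conditioned soma 1 (-2.46) or 2 (-1.99). No member of either list passed, over all genes or adjusted over the list alone.

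By limma 0 genes passed the interaction, with 85 at an unadjusted p under 0.05, 35 higher and 50 lower, and robust moderation also gave 0. Beside Rps14, the largest positive values were those of Zbp1 (10.09, SE 3.13) and the translation termination factor Gspt1 (6.42, SE 1.99), and the largest negative ones those of Sept7 (-7.22, SE 2.22), the deubiquitinase gene Usp9x (-6.25, SE 1.93), Ddx3x (-5.79, SE 1.93) and Sept3 (-5.44, SE 2.25). Polr1d, Hist1h4n and Bex1 also met the naming rule. In home cage 1 and 2 and fear conditioned 1 and 2, Polr1d was listed at 0, 0, 3.65 and 129 in dendrite and 0.280, 73.7, 0.445 and 2.55 in soma, Hist1h4n at 0, 0, 10.9 and 0 and at 12.3, 67.6, 0.587 and 0.195, and Bex1 at 9.30, 6.51, 0.653 and 0 and at 0, 0, 11.7 and 3.40. All 10 had an adjusted p of 0.732. Ttr passed adjusted over its list of 1 gene alone and not over all genes, and in soma was listed at 0 and 0.0473 after fear conditioning against 17.1 and 1.11. In simulated data with this spread the test recovered 1.2% of genes changed by 6 on the log2 scale.

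The comparison of dendrite immunoprecipitates with dendrite supernatants asked which mRNAs the tagged ribosomes hold more or less of than the unbound RNA. Depth differed between these fractions. The dendrite supernatants listed 13164 and 10785 genes above 0 at 34.9 and 35.3 M mapped fragments. The dendrite immunoprecipitates listed 3344, 4695, 12205 and 6147 at 5.68, 17.6, 21.1 and 18.5 M. Marker lists of oligodendrocytes, astrocytes and interneurons were lower on the ribosomes at the preset correlation and did not pass with an estimated one. Oligodendrocyte markers fell with all 8 tested members negative and a median of -1.95 (adjusted p = 3.49e-06; adjusted p = 0.137 with an estimated correlation). Mbp, a myelin protein (chromosome 18, 82644515 to 82755029), had 12.9 ± 8.71 (SD, n = 4) in immunoprecipitates and 51.6 ± 13.2 (SD, n = 2) in supernatants, a log2 difference of -2.11 (SE 1.34). Astrocyte markers fell with all 15 negative and a median of -1.58 (adjusted p = 5.89e-06; adjusted p = 0.137 with an estimated correlation). The glial filament gene Gfap had 2.01 ± 2.35 against 9.70 ± 4.85 (log2 -2.14, SE 0.87), and Glul had 46.3 ± 18.0 against 90.2 ± 3.84. Interneuron markers fell with 6 of 7 negative and a median of -1.41 (adjusted p = 0.00195; adjusted p = 0.137 with an estimated correlation). Gad1, which makes the transmitter GABA, was listed at 0.295, 0, 1.49 and 0.528 in immunoprecipitates and at 4.46 and 6.76 in supernatants. Microglia markers had a median of -1.48 and did not pass (adjusted p = 0.0844); C1qa, under the expression minimum, was listed at 0, 0, 0.458 and 0 against 1.43 and 2.43.

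Camk2a, a marker of the targeted neurons, had 259 ± 191 (SD, n = 4) in dendrite immunoprecipitates and 111 ± 30.3 (SD, n = 2) in supernatants, a log2 difference of 0.87 (SE 1.19) with a limma adjusted p of 1. CA1 pyramidal neuron markers as a list had a median of -0.20 (adjusted p = 0.947). Cytoplasmic ribosomal proteins rose on the ribosomes with 59 of 77 positive and a median of 0.80 (adjusted p = 3.16e-06; adjusted p = 0.402 with an estimated correlation), among them Rpsa with 782 ± 388 against 133 ± 66.8. The mixed list named translation elongation factors rose with 11 of 13 positive and a median of 1.06 (adjusted p = 0.00157; adjusted p = 0.137 with an estimated correlation). With quantile normalization neither cytoplasmic ribosomal proteins (median 0.40, adjusted p = 0.0561) nor translation elongation factors (0.65, adjusted p = 0.200) passed. Eef1a1 had 569 ± 370.1 against 83.0 ± 16.1, a log2 difference of 2.53 (SE 1.05). Presynaptic vesicle and active zone genes fell with 18 of 19 negative and a median of -1.03 (adjusted p = 0.00195; adjusted p = 0.346 with an estimated correlation; adjusted p = 0.105 with no expression minimum), with Snap25 at 223 ± 411 against 84.4 ± 24.5. The presynaptic list was not called with the replicate block. No member of these lists passed, over all genes or adjusted over the list alone. Without the home cage dendrite supernatant, with which the fear conditioned dendrite immunoprecipitate 1 correlated, astrocyte markers still passed (median -1.50, adjusted p = 0.000311). The medians of oligodendrocyte markers (-1.69), interneuron markers (-1.36), presynaptic vesicle and active zone genes (-0.06), translation elongation factors (0.49) and cytoplasmic ribosomal proteins (0.14) then no longer passed. Without the fear conditioned dendrite supernatant the presynaptic median was -1.71.

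By limma 2 of 2972 genes passed and both were lower on the ribosomes, with 125 at an unadjusted p under 0.05, 26 higher and 99 lower. Gm3168 (chromosome 8, 125949774 to 125958050) was listed at 0 in all 4 dendrite immunoprecipitates and at 4923 and 106 in the supernatants (adjusted p = 0.00783). AK193394, which overlaps it on the other strand (125951538 to 125951787), was listed at 0 in all 4 and at 22.4 and 30.8 in the supernatants (adjusted p = 0.0227). Both fell outside the naming rule and are named after their values were seen; because they overlap, their reads cannot be told apart without strand, and in the single-end table both were higher in the immunoprecipitates. In the single-end run Gm3168 took 65.9% of the summed FPKM of home cage dendrite immunoprecipitate 1 and 41.9% of 2. It took 45.6% of fear conditioned dendrite immunoprecipitate 2. Both calls therefore hold for the paired-end run alone and do not show that these RNAs are depleted on ribosomes. Of genes that met the rule without passing, Rbm25, a splicing factor, had 105 ± 114 against 0.192 ± 0.177 (log2 4.90, SE 1.87). Mdm2, the ubiquitin ligase of p53, had 69.9 ± 81.6 against 0.821 ± 0.810 (log2 4.79) and the nucleolar protein gene Ncl 161 ± 99.1 against 3.85 ± 3.05 (log2 4.63). Anp32b had a log2 difference of 4.59 (SE 1.38) and Smc1a, a cohesin subunit, of 4.47 (SE 1.73). In the other direction, Hsbp1 had -4.09 (SE 1.20), Sox2ot -3.62 (SE 0.91), Slc22a17 -3.50 (SE 1.24), Dcdc2a -3.19 (SE 0.96) and Stx4a, a membrane fusion protein, -3.16 (SE 0.82). In simulated data with this spread the test recovered 2% of genes changed by 4 on the log2 scale and 30.4% at 6.

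The soma comparison set 4 immunoprecipitates against 1 supernatant, which was assumed to vary like the other groups. Camk2a had 30.8 ± 15.9 (SD, n = 4) in immunoprecipitates and 46.6 in the supernatant, Gfap 0.307 ± 0.237 against 0.551, and Mbp 10.1 ± 14.3 against 5.99. Gad1 was listed at 0, 0, 0.223 and 0.139 against 1.33, and C1qa at 0, 0, 0.0405 and 0 against 0.0511. Mdm2 had 148 ± 242 against 0.170 (log2 4.80, SE 2.06), the protease gene Ctse 20.8 ± 11.1 against 0.0511 (log2 3.83, SE 1.53) and 6820431F20Rik 11.2 ± 8.72 against 1.01 (log2 2.97, SE 1.34). Arhgap11a was listed at 3.46, 27.3, 33.4 and 4.61 against 0 in the supernatant. Rbm4b had a log2 difference of -4.20 (SE 1.11), Ccl27a of -3.92 (SE 1.08) and FKBP12-T1 of -3.78 (SE 1.45), while Snora81 and AK189601 were listed at 0 in all 4 immunoprecipitates and at 17.9 and 11.04 in the supernatant.

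No gene or list passed in this soma comparison. By limma 0 of 2972 genes passed, with 30 at an unadjusted p under 0.05, 4 higher and 26 lower, and robust moderation also gave 0. Cytoplasmic ribosomal proteins had 60 of 77 positive and a median of 0.62 (adjusted p = 0.0859), CA1 pyramidal neuron markers 10 of 13 negative and a median of -0.76 (adjusted p = 0.0966), and interneuron markers 6 of 7 negative and a median of -0.24 (adjusted p = 0.0966). Oligodendrocyte markers had a median of 0.05 and astrocyte markers of -0.19 (adjusted p = 0.7997 and 0.527). In simulated data the soma test recovered 7.6% of genes changed by 6 on the log2 scale and made 70 false calls over 5 runs, so it did not hold its error rate.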

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

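The tests on neuropil RNA, on astrocyte markers without 1 library and on the home cage soma library were chosen only after the results were seen, as was the use of the rest of the 3′ UTR; the tests on carry-over, incomplete immunoprecipitation, coding length and other splits were written first.

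Among 28 groups of 4 libraries, 2 held a library far from the others, and chance marks about 1 in 20 such groups. Arc in dendrite immunoprecipitates was highest in fear conditioned 2, whose gap to the next library was 0.855 of the range on the log2 scale. The mean score of voltage-gated ion channels in dendrite immunoprecipitates set home cage 1 apart, with a gap of 0.850 of the range. The difference after fear conditioning differed between dendrite and soma for cytoplasmic ribosomal proteins (median 1.81) and for cytosolic heat shock genes (median -2.39), by camera on the interaction with the preset correlation (adjusted p = 0.721 for both with an estimated correlation). The ribosomal call was lost without the home cage soma immunoprecipitate 2, and the heat shock call in 7 of the 8 fits that left out 1 library. In the rest of the 3′ UTR, which the comparisons above do not use, Atp9a (chromosome 2, 168459938 to 168567631) passed the interaction with an adjusted p of 0.00312 by limma. It was listed at 613 and 499 in home cage dendrite, at 233 and 820 in fear conditioned soma and at 0 in the other 4 immunoprecipitates. AK206940 (chromosome 7, 28424062 to 28424467) passed the soma comparison with the supernatant with an adjusted p of 0.0298, and was listed at 141 in that supernatant and at 0 in the other 10 libraries. A lone library assumed to vary like the others gives such calls readily, and the test of this comparison did not hold its error rate on simulated data.

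The paired-end fear conditioned dendrite immunoprecipitate 1 resembled the home cage dendrite supernatant. Of the genes above 0 in that supernatant and at 0 in all remaining libraries, 49.5% were above 0 in this immunoprecipitate, against at most 12.4% in any other immunoprecipitate and 8.27% in its own single-end run. Incomplete immunoprecipitation is argued against as the source of these private genes, because the same share for genes private to the fear conditioned dendrite supernatant was 10.1%. This library has no supernatant of its own here, and the test leaves out RNAs common to the supernatants, so it cannot speak for those. Carry-over of supernatant reads in the paired-end run may account for the resemblance. The bound written beforehand asked for over 50%, which was narrowly missed, so carry-over stays open. A single gene goes against it. Gm3168 took 25.4% of the summed FPKM of that supernatant in the paired-end run and was listed at 0 in this immunoprecipitate. No biological explanation was tested.

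Astrocyte markers were higher in dendrite than in soma immunoprecipitates. The library that resembled a supernatant is argued against as the cause, since without it the median was 2.02 and the list still passed at the preset correlation (adjusted p = 0.000729). With all 8 libraries it did not pass with an estimated correlation (adjusted p = 0.188) or by fry (adjusted p = 0.0854). Carry-over of unbound neuropil RNA could contribute, since the same markers differed by 2.54 (median log2) between the dendrite supernatants and the soma supernatant, more than the 1.00 in the immunoprecipitates over the 15 markers tested with supernatants. Oligodendrocyte markers, however, differed by 2.12 between the supernatants and by 0.20 between the immunoprecipitates, so the test does not decide, and a difference in tagged ribosomes between the dissected parts stays open and untested.

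Ribosomal protein mRNAs were lower in fear conditioned than in home cage soma immunoprecipitates. Coding length is argued against as the whole cause: the list's median of -1.35 lay at percentile 0.02 of 10000 random lists matched on mean and length. The home cage soma immunoprecipitate 2 alone may account for the pattern, since without it the adjusted p was 0.806 and the median -0.10. The interaction call on cytoplasmic ribosomal proteins was lost without it (adjusted p = 0.588), with a median of 1.02 against 1.81 with it and -0.28 for all genes without it. A biological effect of fear conditioning stays open: the fit without that library did not pass, and it left 1 home cage soma immunoprecipitate.

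For dendrite against soma, chance was examined over the 35 splits of the 8 immunoprecipitates into 4 and 4, in a fit with 2 groups. The number of genes says nothing about chance, because the real split gave 0 and the highest of the others 0, so that all 35 necessarily gave as many. For the number of lists chance cannot be excluded, with 5 in the real split and 5 in the highest other, so that 2 splits gave as many. Outside the tests written first, the real split had 125 genes at an unadjusted p under 0.05 against 118 in the highest other, and no other split had as small a p for astrocyte markers. The main fit had 130 such genes, 4.43% of those tested, below the 5% that chance alone gives at this threshold. Astrocyte markers were the strongest list in these same data, so their place among the splits says nothing about chance.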

How the results depend on the processing

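The use of the rest of the 3′ UTR and the fits of gene lists with 1 library left out were chosen after the data were seen; the other alternatives were planned. The count of 0 genes stayed at 0 under robust moderation, both pseudocounts, both expression minimums, quantile normalization and the mean of both tables in the 4 comparisons among immunoprecipitates. FPKM as deposited gave 1 gene between dendrite and soma and 1 after fear conditioning in soma (Atpase6 in both), the single-end table gave 1 between dendrite and soma (Mir1906-1), and the rest of the 3′ UTR gave 1 in the interaction. In these cases the cause was not tested.

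For dendrite immunoprecipitates against supernatants, the 2 genes became 1 with a pseudocount of 0.1, 1 with one of 5, 1 with an expression minimum of 5, 367 with no minimum, 10 in the single-end table, 0 with the mean of both tables and 0 in the rest of the 3′ UTR. In soma the 0 became 928 with no minimum, 1 with a minimum of 5, 1 with quantile normalization, 10 in the single-end table, 4 with the mean of both tables and 1 in the rest of the 3′ UTR. With no minimum, 366 of the 367 genes in dendrite and all 928 in soma were lower on the ribosomes. AK193394 reversed to 5.09 in the single-end table and 0.16 with the mean of both tables, and Gm3168 to 4.01 in the single-end table. The cause was not tested.

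With an estimated correlation 0 lists passed in each comparison. With fry 0 passed between dendrite and soma, in soma after fear conditioning and in the interaction, and 4 in dendrite against the supernatant (interneuron, astrocyte, oligodendrocyte and microglia markers). The single-end table gave 1 list after fear conditioning in dendrite (ribosomal proteins), 1 in the interaction and 3 in soma against the supernatant; FPKM as deposited gave 1 in the interaction and 1 in soma against the supernatant; the rest of the 3′ UTR gave 0 after fear conditioning in soma and 1 in the interaction, textbook dendritic mRNAs, which had not passed. Between dendrite and soma it gave 6 lists, of which only glutamate receptors and astrocyte markers had passed in the coding part; the others were postsynaptic density scaffolds, presynaptic genes, CA1 pyramidal neuron markers and oligodendrocyte markers. Heat shock genes reversed in the interaction in the rest of the 3′ UTR (median 1.48), where textbook dendritic mRNAs also had a median of -0.15 between dendrite and soma. The cause was not tested. Astrocyte markers passed between dendrite and soma, and against the supernatant in dendrite, in all 11 settings other than the list tests and in every fit with a library left out. Voltage-gated ion channels passed in 4 of 10 such settings, and heat shock genes in the interaction in 2 of 10.

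Leaving out 1 library gave 0 to 165 genes between dendrite and soma, 0 to 0 after fear conditioning in dendrite, 0 to 226 in soma, 0 to 134 in the interaction, 0 to 1 in dendrite and 0 to 0 in soma against the supernatant. The highest counts came without the home cage soma immunoprecipitate 2, and 81 and 99 in soma without home cage 1 and fear conditioned 2. Of these calls 98.2 to 100% were highest, or at 0, in the library left alone in its group, which a lone library assumed to vary like the others produces by construction. The lists ranged from 3 to 6, 0 to 0, 0 to 2, 0 to 2, 1 to 7 and 0 to 2 in the same order.

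Of 1247 pairs of a named gene and a setting, 1215 kept their side of the threshold, 15 came to pass, 14 no longer passed and 3, of genes that had passed, reversed; the sign turned in 22 pairs in all. Only 2 named genes, Gm3168 and AK193394, had passed. Most pairs therefore kept their side by not passing again, and the 14 lost and 3 reversed pairs all fall on those 2 genes. The replicate block gave 1 gene between dendrite and soma (Atpase6), 1 list in the interaction and 1 gene in dendrite against the supernatant (Gm3168), where presynaptic genes were not called (adjusted p = 0.0582 for presynaptic vesicle and active zone), and changed no other count by over 1.5 times. Between dendrite and soma it called 4 lists in place of 6, and textbook dendritic mRNAs and voltage-gated ion channels were lost. The pairing check, added after the data were seen, gave correlations of -0.019 to 0.063 between immunoprecipitates that share a number. Between dendrite immunoprecipitates and supernatants of one name it gave -0.0028 and -0.0088. Replicate immunoprecipitates themselves had an r of only 0.200 to 0.418, so values near 0 do not show that libraries of one number are unpaired. Dendrite and soma of fear conditioned 1 and 2 gave 0.044 and 0.054, against at most 0.0048 and 0.0013 with another name. Those of home cage 1 and 2 gave 0.028 and -0.019, against 0.031 and 0.036. Xist, picked after its values were seen, was listed in dendrite and soma at 23.7 and 12.2 in home cage 1 and 15.3 and 42.5 in fear conditioned 1. It was listed at 0.148 and 0.263 in home cage 2 and 2.54 and 0.0468 in fear conditioned 2. In the single-end run Xist was listed at 8.35 and 14.6 in home cage 1 and 12.2 and 14.8 in fear conditioned 1. There it was at 0 and 0.218 in home cage 2 and 0.104 and 0.0292 in fear conditioned 2. In both runs Xist was thus higher in every library numbered 1 than in any numbered 2, in dendrite and soma alike. This rests on 1 gene, so whether libraries of one number share a source stays open. The single soma supernatant could not be checked.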

Other observations

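The genes in this part were chosen after their values were seen, and no test of them is given.

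Malat1, a nuclear RNA (chromosome 19, 5795690 to 5802671), was listed at 447, 195, 221 and 74.6 in the dendrite immunoprecipitates and at 751, 810.5, 1449 and 275 in the soma ones. With FPKM as deposited both home cage pairs turned (425 and 285 in dendrite, 370 and 162 in soma) and its log2 difference went from -1.84 to -0.80. In the rest of the 3′ UTR Meg3 (chromosome 12, 110779203 to 110809939) was listed at 0.405, 0.384, 2.82 and 0.0854 in dendrite and at 129.8, 35.2, 208 and 39.9 in soma. Snhg11 there was listed at 0.0630, 0.0800, 9.44 and 0.0899 in dendrite and at 139, 105, 47.3 and 29.2 in soma. In the coding part both overlapped. Meg3 was listed there at 0 in every dendrite library and at 94.0, 0, 3.58 and 0.370 in soma. Snhg11 was listed at 0.267, 0.335, 4.06 and 0 in dendrite and at 550, 0, 86.1 and 27.1 in soma. Coding-part log2 differences were -0.15 for Rian, -0.71 for Mirg, 0.14 for Sox2ot and 0.28 for Xist. Neat1, another nuclear RNA, had a log2 difference of 0.94 in the paired-end table and -0.32 in the single-end table.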
